A study of Populus ussuriensis with 12 samples.

How the data were processed

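Total RNA was sequenced from the outermost 0.5 cm of root tips of Populus ussuriensis, a poplar of northeast Asia, grown in vitro. Plants that were 1 week old were moved for 7 days to agar medium that held 6% PEG6000 or none. PEG is polyethylene glycol, an osmotic agent used to impose a water deficit. Wild-type plants (WT) were compared with plants overexpressing PuC3H35 (OE), a CCCH zinc finger protein. The 12 libraries were grouped by their titles into OE and WT, each with and without PEG, with 3 libraries per group. The genotype labels of the 6 OE libraries carry 6 different numbers, from PuC3H35 to PuC3H40, while the series title names a single overexpression line; the libraries were treated as 1 genotype. No label says that replicates came from separate plants or cultures, so the p-values measure only the spread between these samples, which may be technical.

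The deposited table gives FPKM, values scaled to gene length and library depth, to 4 decimals for 34699 gene identifiers in 12 columns, each named by a sample title. Bowtie2 2.2.3, HISAT2 2.1.0 and HTSeq 0.6.0 are named in the submitters' processing notes, with no role or order. The genome build, the annotation, the strand setting and the treatment of reads that match several genes are not given in the sources used here. Values of near-identical gene copies are therefore uncertain, since their reads could have been split between copies or dropped. FPKM sums per library ran from 610201 to 665551, with the 3 OE PEG libraries highest, and 3077 genes were listed at 0 in every library.

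Depth was recovered from the values themselves. An FPKM is a whole number of reads multiplied by a constant of the gene and divided by a constant of the library, so the steps between low values give reads, relative depth and gene length. Whole reads were assigned to all 34699 genes, those at 0 included. In 99.98% of the 5975 genes used to test it, the implied length was within 0.05 bp of a whole number. For the 16698 genes with a summed FPKM over 50, 99.99% of values were returned by the formula within 0.0001 FPKM or 0.001% of the value. The median recovered length was 1800 bp and 36.8% of lengths were divisible by 3, so the lengths include more than coding sequence. Recovered totals were 27120611 to 37096691 reads per library, and an FPKM of 1 in a gene of median length stood for 48.8 to 66.8 reads. Whether a recovered read is a mate or a whole pair is not given in the sources used here. On a simulated table of 6000 genes, the recovery returned 99.98% of the 4115 genes with over 50 reads exactly. Reads were drawn singly there, while low read numbers in the data were mostly even, so the simulation did not test such numbers. Genes with fewer reads were not scored.

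FPKM is not a count, so the main test was made on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, using a mean-variance trend and two-sided moderated statistics. The fold changes are on this log2(FPKM + 1) scale, which understates the change of weakly expressed genes. Genes with a mean FPKM of at least 1 over the 12 libraries were tested, which kept 22640 and left out 12059. All 4 groups entered a single fit with group means and 8 residual degrees of freedom. The 5 contrasts were OE against WT without PEG, OE against WT under PEG, PEG against control in WT, PEG against control in OE, and the interaction, which is the PEG effect in OE minus that in WT. Adjusted p-values are Benjamini-Hochberg values within a contrast, and a gene was called at an adjusted p under 0.05. A gene called 2-fold also had a log2 fold change of at least 1 in size. In simulated data for OE against WT without PEG, run on 22653 genes with 50 changed genes per size, limma called 74% of genes changed 1.3-fold, 94% at 1.5-fold and 100% at 2-fold and 4-fold. It called 12 of 22453 unchanged genes. The simulated libraries were independent, with the same spread beyond counting for every gene and few changed genes. These calls therefore do not measure the rate of false calls in the real libraries.

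The table holds identifiers with no gene names or descriptions, and no annotation was used here. No gene list was therefore tested, no identifier was given a function, and the level of PuC3H35 itself was not looked up. Identifiers were named by a rule fixed before the data were examined, as were the tests, the groups and most alternatives. Per contrast, the rule took the 2 genes with the largest positive and the 2 with the largest negative log2 fold change. Each had to be called 2-fold and reach a mean FPKM of at least 5 in the higher group. Outside the interaction, all 3 libraries of one group also had to lie above all 3 of the other. A gene named in 2 contrasts counts in both.

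Alternatives covered the pseudocount, the filter on low values, scaling between libraries, the variance model, the libraries in the fit, the threshold, the adjustment, a block for the replicate number, and each library left out in turn. A limma voom fit on the recovered reads and a fit with the gene length trend of each library removed (lowess span 0.3) were added after the data had been seen, as were the alternatives for the interactions and PEG effects of genes named in other contrasts, a pseudocount of 0.5 for single genes and the thinning of recovered reads to equal depth. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 served for the recovery of reads and for tests on gene length and gene order.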

Results

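The data are FPKM values of 34699 genes in root tips of WT and OE poplar plants, each with and without 6% PEG for 7 days, in 3 libraries per group. The study asked how overexpression of PuC3H35 changes the root tip transcriptome and its response to osmotic stress. Recovered depth was 32335715, 28023844 and 36478040 reads for the OE libraries without PEG and 31074615, 30420609 and 37096691 for the OE PEG libraries. It was 27120611, 29815883 and 33167971 for the WT libraries without PEG and 27655859, 32256253 and 31663476 for the WT PEG libraries. The 10 genes with the most reads took 2.37% to 4.13% of a library, the highest shares being those of the WT PEG libraries.

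More genes were detected with PEG and in OE. Genes at FPKM 1 or more in all 3 libraries numbered 20993 in WT without PEG, 21590 in OE without PEG, 21872 in WT under PEG and 22160 in OE under PEG. Genes without a read in any library of the group numbered 5352, 4651, 4965 and 4183 in the same order, fewer where the summed depth of the group was greater. With every library thinned to 27120611 reads, drawn singly, they numbered 5427.6, 4791.6, 5042.6 and 4358.7 (means of 20 draws). Drawn in units of 2 reads, as if mates came in pairs, they numbered 5471.5, 4862.8, 5088.9 and 4409.4. No 2 replicates agreed within sampling noise. Over genes with at least 20 reads in both replicates together, chi-square per degree of freedom between replicates was 2.82 to 4.53, where counting error alone gives 1, or 2 if both mates of a pair were counted. Among genes with over 2000 such reads, the coefficient of variation beyond counting error, with each read taken as independent, was 2.71% to 4.30%. It would be smaller if both mates of a pair were counted.

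The 4 groups separated on the first 2 principal components, which held 63.6% and 23.1% of the variance. On the first, WT without PEG lay at -67.59 to -66.82, OE without PEG at -18.58 to -17.07, WT under PEG at 9 to 9.21 and OE under PEG at 75.63 to 76.30. On the second, the WT PEG libraries stood at 52.68 to 54.08, and the other 9 libraries lay below 0.

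**Figure D1:**
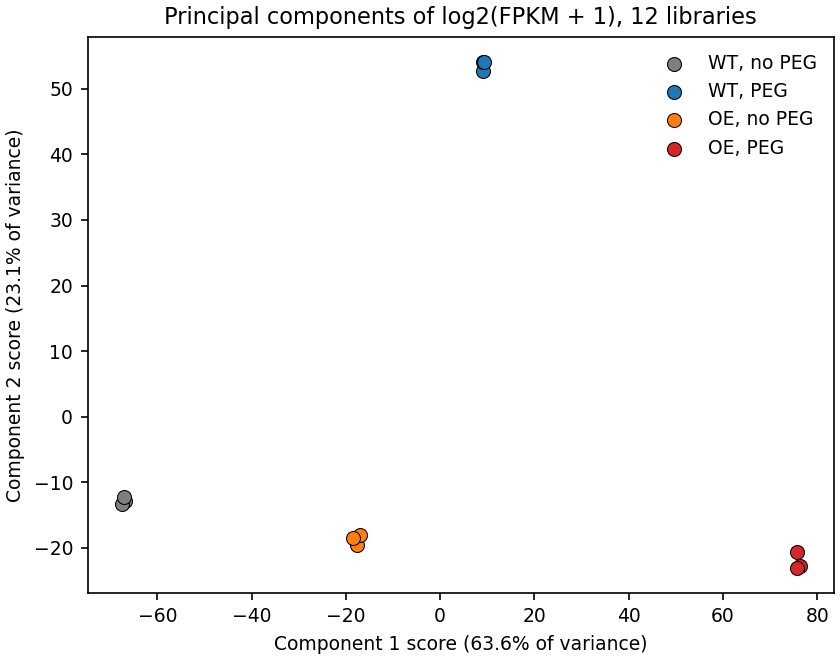
Scores of the 12 libraries on principal components 1 (63.6% of variance) and 2 (23.1%) of log2(FPKM + 1), with a point per library and a colour per group. The 3 libraries of each group lie together, and OE without PEG lies between WT without PEG and WT under PEG on component 1.

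The first comparison asked which transcripts differed between OE and WT root tips on ordinary medium. Potri.008G106400 stood at 65.5 ± 1.93 FPKM in OE and 1.84 ± 0.296 in WT (SD, n = 3 here and for all group values), and Potri.001G107600 stood at 31.2 ± 1.72 and 0.442 ± 0.236. Potri.008G158200 was lower in OE, at 10.3 ± 0.704 against 56.4 ± 0.828, as was Potri.009G070201, at 4.87 ± 0.896 against 28.4 ± 2.14. Differences of at least 2-fold favoured OE, with 882 genes higher and 174 lower.

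The log2 fold changes were 4.55 (SE 0.06, limma adjusted p = 4.6e-16) for Potri.008G106400 and 4.49 (SE 0.09, adjusted p = 7.9e-14) for Potri.001G107600. They were -2.34 (SE 0.06, limma adjusted p = 4.8e-13) for Potri.008G158200 and -2.33 (SE 0.09, adjusted p = 4.7e-11) for Potri.009G070201. All 4 named genes also changed with PEG in WT, in the direction of their difference between OE and WT. Potri.008G106400 reached 103 ± 0.932 FPKM and Potri.001G107600 reached 110 ± 7.40 in WT under PEG, while Potri.008G158200 fell to 14.4 ± 0.391 and Potri.009G070201 to 7.14 ± 0.234. At any size, limma called 12457 of 22640 genes (55.0%), 7168 higher and 5289 lower in OE, with a median absolute log2 fold change of 0.37 among the called genes. With quantile normalization 45.5% of the called genes were higher in OE instead of 57.5%, so the balance of small changes followed the scaling. A pseudocount of 0.1 gave 1593 genes higher and 303 lower at 2-fold.

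The second comparison measured the response to PEG in WT roots. Potri.017G114600 rose from 0.166 ± 0.0167 to 199 ± 3.07 FPKM and Potri.007G114375 from 0.212 ± 0.192 to 120 ± 2.65. Potri.013G128800, an abundant transcript of WT roots without PEG, fell from 665 ± 13.7 to 51.9 ± 0.693, and Potri.005G252250 fell from 103 ± 1.61 to 12.5 ± 2.16. Strong changes were mostly increases, with 1607 genes raised and 265 lowered by at least 2-fold.

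For Potri.017G114600 and Potri.007G114375 the log2 fold changes were 7.42 (SE 0.15, limma adjusted p = 7e-15) and 6.66 (SE 0.09, adjusted p = 1.3e-16). For Potri.013G128800 and Potri.005G252250 they were -3.65 (SE 0.06, limma adjusted p = 4.2e-16) and -2.96 (SE 0.09, adjusted p = 4.9e-13). Both raised genes were also higher in OE than in WT without PEG, at 9.96 ± 3.07 and 12.6 ± 0.908 FPKM. At any size limma called 14627 genes (64.6%), 6775 raised and 7852 lowered. The raised share of 46.3% was 37.4% with quantile normalization and 50.9% with the length trend removed, so the balance is not settled. A pseudocount of 0.1 gave 459 genes lowered at 2-fold, and a minimum mean FPKM of 5 left 979 raised.

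The third comparison measured the response to PEG in OE roots. Potri.003G061200 rose from 1.47 ± 0.723 to 195 ± 5.14 FPKM and Potri.003G061000 from 1.21 ± 0.303 to 123 ± 3.70. Potri.002G060400 fell from 88.7 ± 2.22 to 6.17 ± 0.449 and Potri.001G176000 from 36.5 ± 0.165 to 3.17 ± 0.247. At 2-fold, 1690 genes were raised and 533 lowered.

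The log2 fold changes were 6.36 (SE 0.17, limma adjusted p = 1.9e-13) for Potri.003G061200 and 5.82 (SE 0.15, adjusted p = 2.1e-13) for Potri.003G061000. They were -3.65 (SE 0.06, limma adjusted p = 7.9e-15) for Potri.002G060400 and -3.17 (SE 0.06, adjusted p = 8.1e-15) for Potri.001G176000. In WT the first pair rose as well, from 0.147 ± 0.158 to 20.7 ± 1.60 and from 0.211 ± 0.365 to 19.2 ± 1.73 FPKM. Potri.001G176000 fell only from 52.3 ± 2.86 to 39.1 ± 2.32 in WT. At any size limma called 14625 genes (64.6%), 6915 raised and 7710 lowered. Shorter genes moved up and longer genes down, with Spearman's rho of -0.34 between recovered length and fold change across 22640 genes, which are not independent replicates. The raised share of 47.3% was 35.3% after rescaling to the same FPKM sum, 50.8% with median-of-ratios scaling and 51.6% with the length trend removed. A pseudocount of 0.1 gave 861 genes lowered at 2-fold, and a minimum mean FPKM of 5 left 1060 raised.

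**Figure D2:**
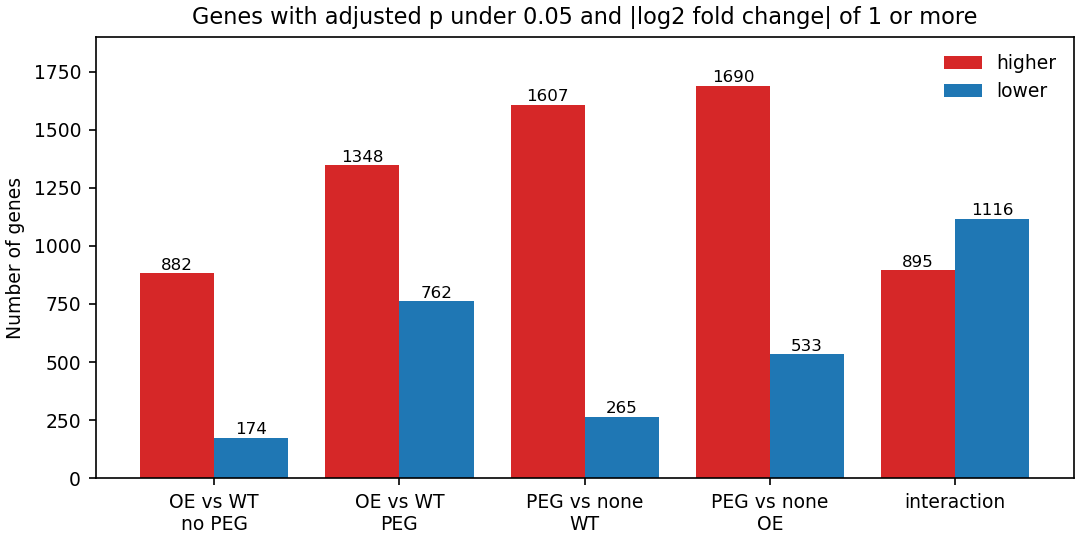
Bars give the number of genes with an adjusted p under 0.05 and an absolute log2 fold change of at least 1, higher (red) and lower (blue), in the 5 contrasts. Higher genes outnumber lower genes in the contrasts of 2 groups, and the interaction has 895 above and 1116 below 0.

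The PEG responses of the 2 genotypes overlapped. Of the 1607 genes raised 2-fold in WT, 853 were raised 2-fold in OE too, where independent lists would share 120.0, and 1321 (82.2%) were called raised in OE at any size. Lists of lowered genes shared 94 of 265 in WT and 533 in OE, where 6.2 would be shared by independent lists. Opposite 2-fold responses were found for 19 genes raised in WT and for 8 lowered in WT. The 853 genes raised in both had median log2 fold changes of 1.93 in WT and 1.76 in OE. Across the 22640 genes the fold changes of the genotypes correlated with Pearson's r = 0.571, with no library shared between them.

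**Figure D3:**
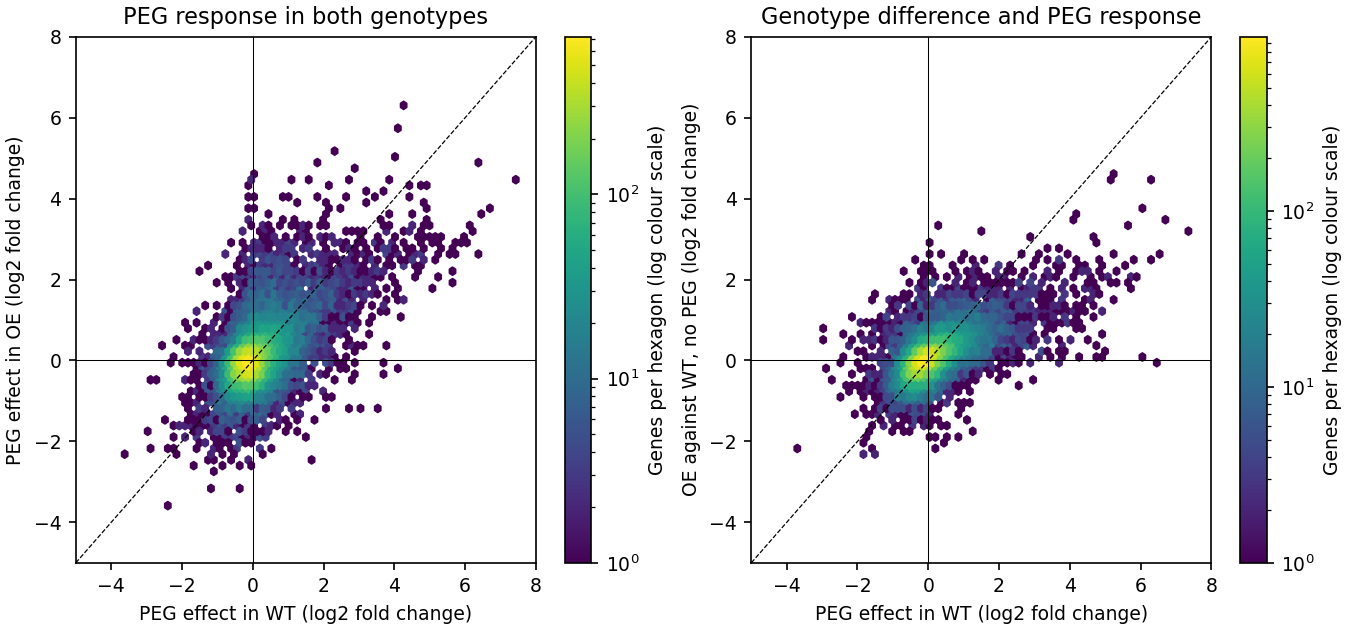
Hexagons show the number of genes (log colour scale) by log2 fold change for PEG in WT (horizontal axis) against PEG in OE (left) and against OE over WT without PEG (right), with the dashed line marking equality. Pearson's r is 0.571 on the left and 0.602 on the right, and the right-hand cloud lies below the dashed line at high PEG effects.

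The fourth comparison asked which transcripts differed between OE and WT under PEG. Potri.003G068900 stood at 113 ± 2.31 FPKM in OE and 0.570 ± 0.168 in WT, and Potri.004G182100 at 117 ± 5.65 and 1.38 ± 0.414. Potri.016G057600 was lower in OE, at 5.31 ± 0.729 against 90.6 ± 1.27, as was Potri.013G049925, at 3.78 ± 0.352 against 62.2 ± 5.55. At 2-fold, 1348 genes were higher and 762 lower in OE.

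For Potri.003G068900 and Potri.004G182100 the log2 fold changes were 6.19 (SE 0.08, limma adjusted p = 5.1e-16) and 5.65 (SE 0.10, adjusted p = 4.7e-15). For Potri.016G057600 and Potri.013G049925 they were -3.86 (SE 0.10, limma adjusted p = 1e-13) and -3.72 (SE 0.07, adjusted p = 9.7e-15). Without PEG, Potri.016G057600 was near the floor in both genotypes, at 0.0514 ± 0.0447 FPKM in OE and 0.0738 ± 0.128 in WT. At any size limma called 15454 genes (68.3%), 8169 higher and 7285 lower in OE. Fold changes correlated with those measured without PEG at r = 0.436 across genes. At 2-fold, 393 genes were higher in OE on both media, where 52.5 would be by independence, 77 were lower on both, where 5.9 would be, and 33 were higher without PEG and lower under PEG. Spearman's rho between gene length and fold change was -0.313 here, against -0.014 without PEG. The higher share of 52.9% was 40.4% after rescaling to the same FPKM sum and 44.9% with quantile normalization, and a pseudocount of 0.1 gave 1152 lower genes at 2-fold.

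**Figure D4:**
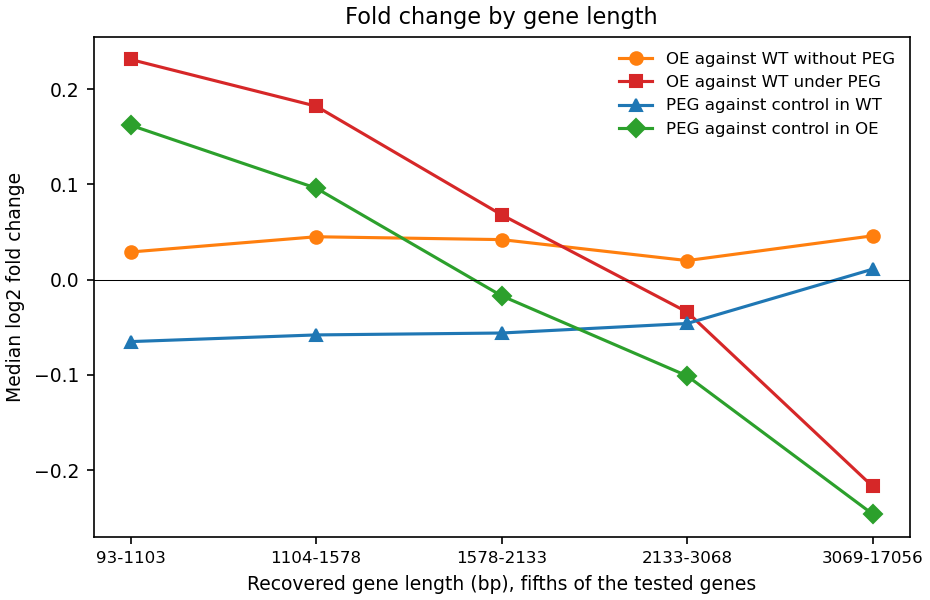
Median log2 fold change in 5 groups of about equal size of the tested genes, ordered by recovered length in bp, with a line per contrast. OE under PEG against WT under PEG falls from 0.231 in the shortest genes to -0.217 in the longest, and PEG in OE falls from 0.162 to -0.246, while PEG in WT runs from -0.065 to 0.011.

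The interaction asked which genes responded differently to PEG in OE and WT. Potri.003G068900 rose from 3.52 ± 0.226 to 113 ± 2.31 FPKM in OE and stood at 0.571 ± 0.0804 and 0.570 ± 0.168 in WT. Potri.014G047000 rose from 0.348 ± 0.0354 to 26.1 ± 1.65 in OE and stood at 0.276 ± 0.0721 and 0.114 ± 0.0596 in WT. Potri.001G032500 rose from 1.83 ± 0.230 to 31.8 ± 1.81 in WT and fell from 5.15 ± 0.561 to 1.83 ± 0.339 in OE. Potri.004G069101 rose from 0.321 ± 0.0502 to 22.4 ± 2.40 in WT and stood at 1.29 ± 0.492 and 1.02 ± 0.485 in OE.

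Interaction log2 fold changes were 4.67 (SE 0.11, limma adjusted p = 9.3e-13) for Potri.003G068900 and 4.52 (SE 0.12, adjusted p = 1.4e-12) for Potri.014G047000. They were -4.66 (SE 0.14, limma adjusted p = 3.3e-12) for Potri.001G032500 and -4.33 (SE 0.24, adjusted p = 1.8e-09) for Potri.004G069101. A group of 547 genes was raised 2-fold in OE with an interaction of at least 2-fold above WT, without a 2-fold rise in WT. The converse group, raised 2-fold in WT with an interaction at least 2-fold below 0, had 379 genes. With voom on the recovered reads the interaction was called in the same direction for 492 of the 547 and 378 of the 379. That check did not cover the 2-fold limits, which on log2(FPKM + 1) can miss rises from near 0. Genes raised 2-fold in WT numbered 2226 with a pseudocount of 0.1 and 2295 with voom, against 1607. In OE they numbered 2076 and 2131, against 1690. Membership of either group therefore does not show that a gene failed to rise 2-fold in the other genotype. Among lowered genes the corresponding groups held 245 in OE and 93 in WT. At any size limma called 12873 interactions (56.9%), 6300 above and 6573 below 0, of which 895 and 1116 were at least 2-fold. The share above 0, 48.9%, was 34.8% after rescaling to the same FPKM sum, which gave 1700 at 2-fold below 0, and 50.9% at a minimum mean FPKM of 5. A pseudocount of 0.1 gave 1780 at 2-fold below 0, a minimum mean FPKM of 5 left 577 above, and rho with gene length was -0.307. With the length trend removed, 761 were at least 2-fold above 0 and 1246 below.

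**Figure D5:**
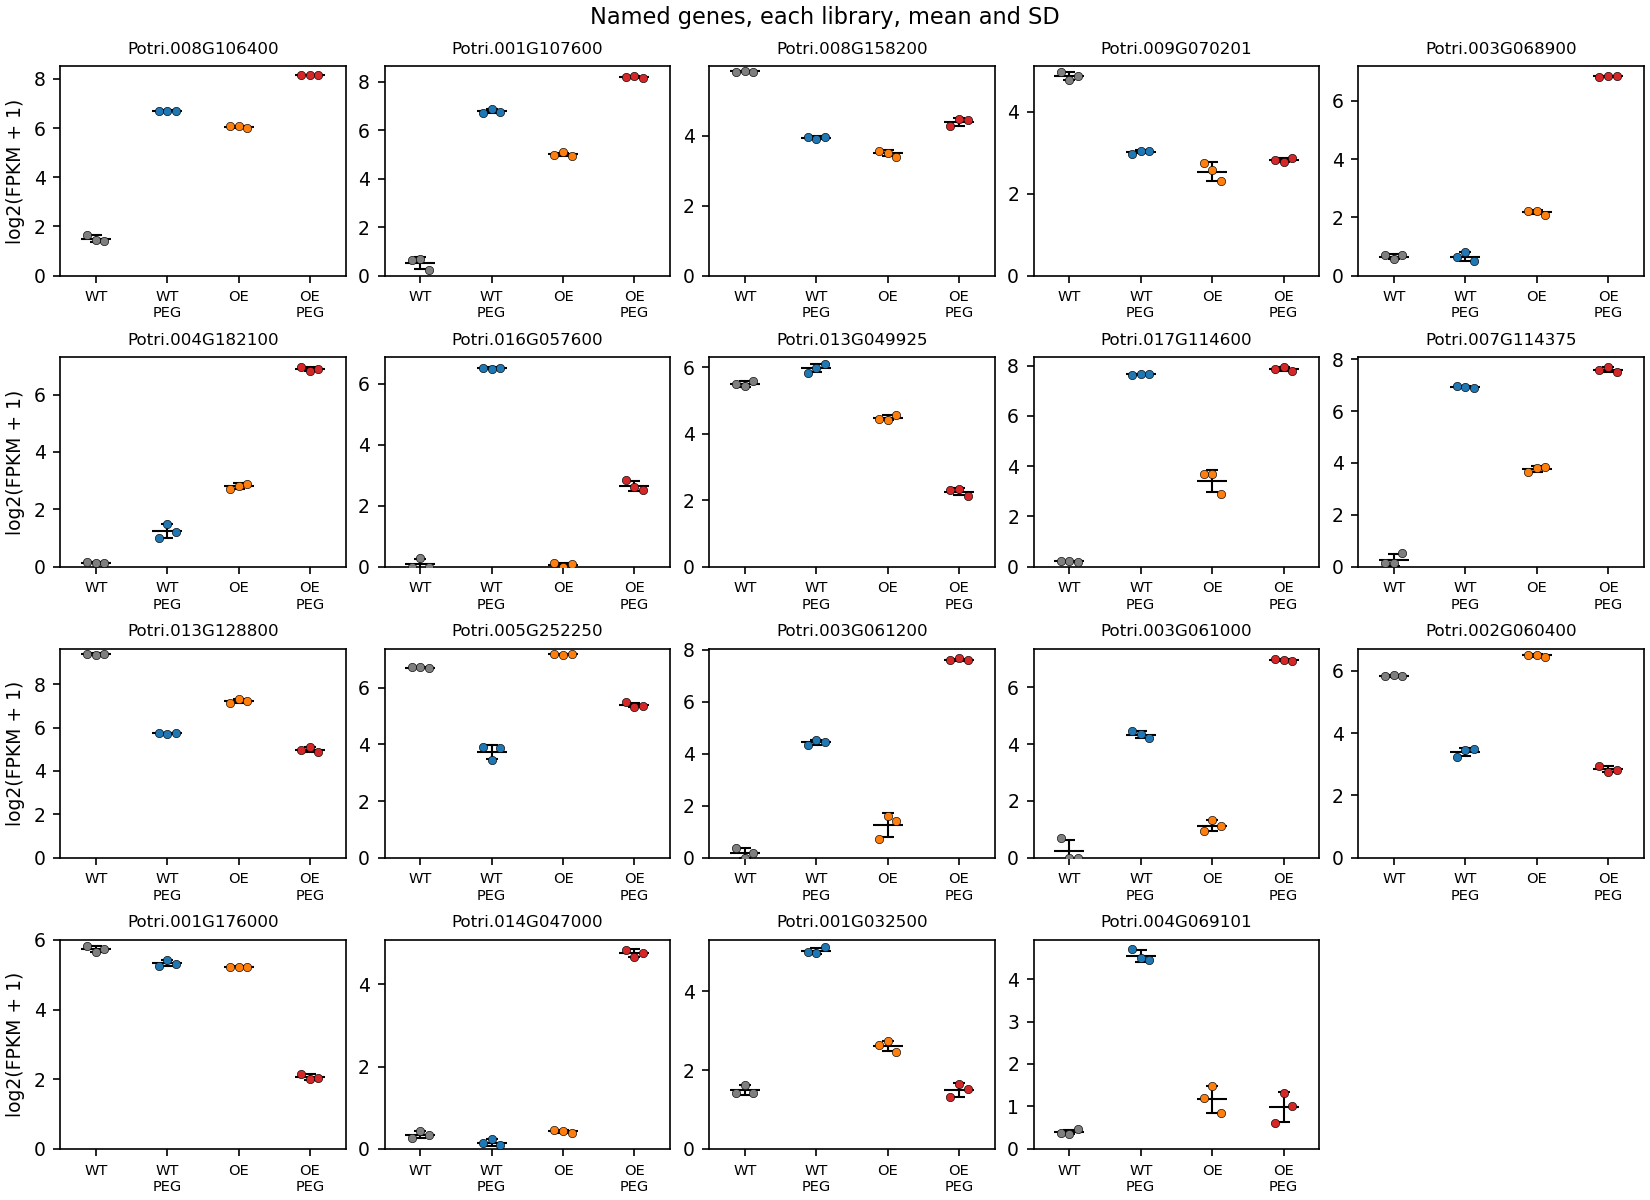
Values of log2(FPKM + 1) in each of the 12 libraries for the 19 genes named by rule, with a point per library and a bar for the mean and SD of 3 libraries. Libraries of a group lie close together relative to the differences between groups, and Potri.003G068900 and Potri.014G047000 stand highest in the OE PEG libraries.

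The last comparison set the difference between genotypes on ordinary medium beside the PEG response of WT. Of the 1607 genes that PEG raised 2-fold in WT, 1344 (83.6%) were called higher and 26 lower in OE than in WT without PEG, with a median log2 fold change of 0.72. Of the 265 genes lowered by PEG in WT, 159 (60%) were called lower and 69 higher in OE. At 2-fold in both contrasts, 534 genes were raised, where independent lists would share 62.6, and 42 lowered, where they would share 2.0. In OE the 1607 genes rose with PEG by a median of 1.06, against 1.54 in WT, and under PEG their median difference between genotypes was 0.00, with 631 called higher and 590 lower in OE. The list sets which genotype has the larger median. The 1690 genes raised 2-fold in OE rose by a median of 1.61 in OE and 1.02 in WT, and differed between genotypes by a median of 1.15 under PEG and 0.62 without it.

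Across all tested genes the correlation of these contrasts was 0.602. They share the WT libraries without PEG, and 100 simulations of unchanged groups against shared controls gave a mean correlation of 0.501 and a highest of 0.532. The covariance was 0.1878, against a simulated mean of 0.00405 and a highest of 0.00458, which leaves a difference of 0.1838. The 3 control libraries were not divided between the 2 contrasts, so part of the overlap counts may come from the shared controls.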

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

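The tests of a mixture of root tips and of noise in the OE libraries without PEG, and the removal of the length trend, the voom fit the alternatives for the interactions of 15 of the 19 named genes and for most of their PEG effects, and the changes in FPKM, were chosen only after the results were seen.

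The response to PEG differed between genotypes by the test of the interaction for 12873 genes and for each of the 19 genes named by rule, whose limma adjusted p for the interaction on log2(FPKM + 1) ran from 9.3e-13 to 9.9e-06. These 19 were picked from the same data for extreme fold changes, so their interactions add no separate evidence to that count. For 3 of the 19, Potri.004G182100, Potri.003G061200 and Potri.003G061000, the call was lost with voom on recovered reads, which shrinks low values less, and for the last 2 also with a pseudocount of 0.1. Of the 12873 genes, voom called 12264 in the same direction and 20 in the opposite one, and a pseudocount of 0.1 called 12522 and 8. Of 100 splits of the 12 libraries, the real one included, 1 gave as many genes, and the highest count of another split was 2835. The other splits mix the groups, so PEG and genotype differences fall within groups and inflate the spread. They therefore do not test for an interaction beside those differences, and chance is not excluded by them. The other 4 contrasts compare 3 libraries with 3, and their 10 splits are too few for a share under 0.05. In each of them 1 of the 10 splits gave as many genes, the real one. Its counts were 12457 for OE against WT without PEG, 15454 under PEG, 14627 for PEG in WT and 14625 for PEG in OE. The highest of the other splits gave 0, 0, 1 and 0 genes.

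Among the named genes, PEG raised Potri.003G068900 (interaction log2 fold change 4.67) and Potri.014G047000 (4.52) in OE, while their changes of -0.01 and -0.19 in WT did not pass the test (limma adjusted p = 0.96 and 0.058). Of 13 alternatives for each, 1 called the first lower in WT (-0.44, quantile normalization). The second was called lower by 5, quantile normalization (-0.58), pseudocounts of 0.5 (-0.34) and 0.1 (-0.83), and the fits without WT control library 1 (-0.23) or WT PEG library 2 (-0.24). Potri.004G182100 (2.99), Potri.003G061200 (2.11) and Potri.003G061000 (1.73) rose in both genotypes from values near 0 in WT, at 0.104 ± 0.0104, 0.147 ± 0.158 and 0.211 ± 0.365 FPKM (SD, n = 3), where the pseudocount of 1 compresses the rise. With a pseudocount of 0.1 their interactions were 1.45, 0.48 and -0.05 (limma adjusted p = 6.6e-05, 0.51 and 0.96), and with voom 0.73, -0.18 and -1.02 (adjusted p = 0.23, 0.84 and 0.23), so the difference held with the lower pseudocount for the first alone and with voom for none of the 3. In FPKM the 3 rose more in OE, by 111, 194 and 122 against 1.27, 20.6 and 19 in WT. Potri.008G106400 (-3.09), Potri.001G107600 (-3.08), Potri.017G114600 (-2.97), Potri.007G114375 (-2.84) and Potri.016G057600 (-3.84) rose in both genotypes, by a smaller ratio in OE. In FPKM the first 4 of these 5 rose more in OE, by 221 ± 1.19, 264 ± 4.93, 222 ± 6.81 and 179 ± 7.52 against 101 ± 0.564, 110 ± 4.27, 199 ± 1.78 and 120 ± 1.53 in WT (SE, n = 3), and they were already higher in OE before PEG, by 4.55, 4.49, 3.19 and 3.5 on the log2 scale. For Potri.017G114600 the difference between genotypes under PEG did not pass the test (0.22, limma adjusted p = 0.2). Potri.001G107600, Potri.017G114600 and Potri.007G114375 (1062, 808 and 695 bp) lie in the shortest of 5 length groups. That group was higher in OE under PEG by a median of 0.231, so these rises were not separated from the trend with gene length. As a ratio the fall with PEG was smaller in OE for Potri.013G128800 (1.39) and Potri.005G252250 (1.17), although in FPKM the second fell by 103 in OE and 90.6 in WT, and it was larger in OE for Potri.002G060400 (-1.20) and Potri.001G176000 (-2.76). Directions were opposite for 3 genes. Potri.008G158200 (2.80) fell in WT and rose in OE, by 0.90, and Potri.013G049925 (-2.70) and Potri.001G032500 (-4.66) rose in WT, by 0.47 and 3.54, and fell in OE. Potri.009G070201 (2.13) fell in WT, and its change of 0.29 in OE (limma adjusted p = 0.014) became 0.13 (adjusted p = 0.23) with the length trend removed, so no rise is claimed. Potri.004G069101 (-4.33) rose in WT, and its change of -0.19 in OE did not pass the test (limma adjusted p = 0.34).

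Genes that PEG raised in WT stood partway up in OE without PEG, with 1344 of 1607 called higher and a correlation of 0.602 across genes. Shared WT control libraries are argued against by the covariance of 0.188, far above the highest simulated 0.00458. Fold changes hardly followed gene length in either contrast (Spearman's rho of -0.014 for OE against WT without PEG and 0.037 for PEG in WT). Removing the length trend could therefore change little, and the correlation was 0.604 afterwards. Noise in the OE libraries without PEG would push the correlation with the PEG response within OE below 0, and it was 0.363. If the OE tips were a mixture of unstressed and PEG-like WT tips and nothing else differed, each gene would show the same mixing fraction. The SD of this fraction over genes was 9.3 times its median standard error (6.2 times with a spread taken from the interquartile range). Its median was 0.28, with a range from the 10th to the 90th percentile of 0.04 to 0.81. These values argue against such a plain mixture alone. A mixture with further differences between genotypes would also give unequal fractions, so it stays open. As a hypothesis, OE roots may hold part of the PEG response on ordinary medium, but a difference in growth stage, culture or library batch between OE and WT plants was not tested and stays open.

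Short genes were higher and long genes lower in the OE PEG libraries, with rho of -0.34 against OE without PEG and -0.313 against WT under PEG. The pattern does not rest on a few abundant genes (-0.339 without the 100 genes with the most reads), on low values (-0.385 at a mean FPKM of at least 10) or on a single library (-0.299 in the weakest of 3). Fragmentation or size selection in these libraries predicts the trend among genes under 2-fold in every contrast, where it was -0.362. It was also predicted to differ among the 3 libraries, which was not seen (rho of -0.313, -0.313 and -0.299 against WT under PEG), but a preparation shared by the group would act alike on all 3, so library preparation and the group cannot be told apart. A biological shift with length in OE under PEG was not tested and is open too.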

How the results depend on the processing

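The fits on recovered reads and with the length trend removed, and most alternatives for interactions and PEG effects of single genes, were chosen after the data had been seen. Counts of called genes stayed within 1.5 times their reported value under all settings but the 2-fold threshold. With each library left out in turn they ran from 11401 to 12537 for OE against WT without PEG, 14457 to 15466 under PEG, 13640 to 14592 for PEG in WT, 13602 to 14690 for PEG in OE and 12133 to 12580 for the interaction. Over the 15 other settings (14 for the interaction) the ranges were 9690 to 13081, 11589 to 17246, 10895 to 16190, 10802 to 16371 and 10003 to 13852. A 2-fold threshold gave 1056, 2110, 1872, 2223 and 2011 genes, a stricter rule by construction. Of 1024 values under alternatives for called effects of named genes, 1016 kept their direction and passed the threshold, 5 kept the direction only and 3 reversed. Of these 8, 3 are the PEG effect in OE of Potri.009G070201, at 0.16 without the third OE control library, 0.36 with voom and 0.13 with the length trend removed. The other 5 are interactions of genes near 0 in WT without PEG, 0.73 for Potri.004G182100 with voom, 0.48 and -0.18 for Potri.003G061200 and -0.05 and -1.02 for Potri.003G061000 with a pseudocount of 0.1 and voom. Left out of these are 3 PEG effects that were not called, of Potri.003G068900 and Potri.014G047000 in WT and Potri.004G069101 in OE. Of their 39 values 6 passed the threshold and 4, all of the first, had the other sign. The majority of called genes, higher or lower, turned in 1, 2, 1, 3 and 3 settings for the 5 contrasts in the order above, the 2-fold threshold aside. Depth limits low values most, since an FPKM of 1 at median length is 48.8 to 66.8 reads.

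Counts at 2-fold moved more. A pseudocount of 0.1 gave 1593 higher and 303 lower for OE against WT without PEG, 1152 lower under PEG, and 459, 861 and 1780 lower for PEG in WT, PEG in OE and the interaction. The voom fit gave 1678 and 327, then 1212, 489, 907 and 1882. Both leave less shrinkage at low FPKM by construction. A minimum mean FPKM of 5 gave 979 and 1060 raised in WT and OE and 577 interactions above 0, from fewer genes tested. Rescaling to the same FPKM sum gave 1700 interactions below 0, and moved the median of all genes to -0.126 for PEG in OE and -0.115 for the interaction. Quantile normalization moved it to -0.113 for PEG in WT. With the length trend removed, 1232 genes were higher and 829 lower at 2-fold for OE against WT under PEG, against 1348 and 762. Interactions at 2-fold were then 761 above and 1246 below 0, against 895 and 1116. Splits of called genes were 7168 and 5289 for OE against WT without PEG, and 5592 and 6694 after quantile normalization. After rescaling they were 6198 and 9131 for OE against WT under PEG, 5375 and 9858 for PEG in OE and 4527 and 8498 for the interaction, against 8169 and 7285, 6915 and 7710, and 6300 and 6573.

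The correlation of PEG responses between genotypes, 0.571, was 0.611 with a pseudocount of 0.1, 0.587 at a mean FPKM of at least 5, 0.536 after quantile normalization and 0.582 with the length trend removed. That of the genotype difference between media, 0.436, was 0.47 at a mean FPKM of at least 5 and 0.41 after quantile normalization. That of genotype difference and PEG response, 0.602, was 0.684, 0.614 and 0.549 with the first 3 settings. The cause was not tested.

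With the replicate number as a block, the replicate block fit called 12357, 15362, 14526, 14559 and 12713 genes and changed no named gene's call. Deviations of same-numbered libraries of different groups correlated at -0.07 to 0.10 over 18 pairs, none over 0.1, so no strong shared deviation was seen. The labels do not say whether a number marks a shared day or plant, so pairing stays unknown. Gene list alternatives (estimated correlation, fry, block) were not run, because nothing used here pairs identifiers with names.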

Other observations

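The choice of the 4 genes named for little response to PEG, the test of gene order against random orders, the thinning of reads to equal depth and the tests of even read numbers were made only after the results were seen.

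A small set of genes differed between genotypes with little response to PEG on the log2(FPKM + 1) scale. Of the genes at least 2-fold apart in OE and WT on both media, 27 that were higher and 21 that were lower in OE had PEG effects under 0.5 in log2 size in both genotypes. The 2 with the largest differences upwards were Potri.006G166701 and Potri.006G166800. Potri.006G166701 stood at 11.1 ± 0.554 FPKM in OE without PEG and 11.5 ± 1.01 with it, against 0.182 ± 0.123 and 0.365 ± 0.121 in WT (SD, n = 3; limma adjusted p = 2.3e-12 and 9.2e-13). Potri.006G166800 stood at 7.96 ± 0.619 and 6.71 ± 0.617 in OE, against 0.161 ± 0.0598 and 0.242 ± 0.0303 in WT. In WT both genes were near 0, where the pseudocount of 1 compresses any change. Their PEG effects of 0.21 and 0.10 in WT therefore do not show a lack of response. In the other direction, Potri.002G201800 stood at 9.47 ± 1.54 and 7.01 ± 0.359 in OE against 45.7 ± 2.58 and 51.7 ± 3.96 in WT. Potri.006G171300 stood at 3.08 ± 0.556 and 2.52 ± 0.118 in OE against 14.5 ± 1.45 and 15.5 ± 2.95 in WT.

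Genes without a read in WT root tips on ordinary medium appeared in the other groups. With no read in any of the 3 WT libraries without PEG, 180 genes had at least 10 reads in every OE PEG library, 93 in every WT PEG library and 19 in every OE library without PEG. In the reverse direction, 6 genes without a read in the OE PEG libraries had at least 10 reads in every WT library without PEG. With all libraries thinned to 27120611 reads, drawn singly, these 4 counts were 162.8, 87, 14.6 and 4.8 (means of 20 draws). Drawn in units of 2 reads, as if mates came in pairs, they were 174.6, 94.2, 17.8 and 5.4. Of the 853 genes raised 2-fold by PEG in both genotypes, 531 were called higher and 134 lower in OE than in WT under PEG, with a median log2 difference of 0.49. The same genes were already apart without PEG, with 719 higher and 17 lower in OE and a median of 0.84, and of their interactions 387 were called below 0 and 177 above.

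Genes with adjacent identifiers tended to rise together. Among 1602 genes raised 2-fold by PEG in WT whose identifiers could be ordered, 267 pairs were adjacent among the tested genes, against a mean of 113.8 and a highest of 143 in 1000 random orders, so an arrangement by chance is argued against. The correlation of fold changes was 0.135 for adjacent genes, 0.070 at 2 steps, 0.054 at 3 and 0.008 at 5. Reads shared between near-identical neighbouring copies could add to this, and where the lengths differed by over 1.5 times the ratio of observed to permuted pairs was 1.5 instead of 2.35 (104 pairs, highest of 1000 random orders 100), which leaves the share of such reads open. Over the lists of raised and lowered genes of the 4 contrasts the ratio was 1.43 to 3.89 for pairs of unlike length and 2.35 to 10.29 for all pairs, and 4 of these 8 lists, the one at 3.89 with 3 pairs included, did not exceed their highest random order for pairs of unlike length. Identifier order was taken as position and not checked against an annotation.

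Among genes with over 200 reads in some library, values of 2 or 4 recovered reads were listed 299 times and values of 1 or 3 reads 55 times, a ratio of 5.44. A read step recovered too small by a factor of 2 would double every read number of a gene, but in the 16698 genes with an odd value between 200 and 2000 reads the ratio was 5.66 (232 and 41 values).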
